A study of Drosophila melanogaster with 16 samples.

How the data were processed

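RNA sequencing libraries were made from the heads of male Drosophila melanogaster flies, collected 5 to 8 days after eclosion and kept on standard food at 25 °C. The flies model the C9ORF72 form of frontotemporal dementia and amyotrophic lateral sclerosis, in which a GGGGCC repeat within an intron of that gene is expanded. They expressed a transgene with a short repeat (5R, the control) or a long repeat (160R), inserted on chromosome 2 or on chromosome 3. The labels give 4 groups (Chrom2-5R, Chrom2-160R, Chrom3-5R and Chrom3-160R) with 4 libraries each, 16 in all. Per the labels, total RNA was extracted with Trizol from heads frozen in liquid nitrogen, and the libraries kept the strand and were not selected for poly(A) tails. Unspliced and nuclear RNA can therefore contribute to the values.

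The deposited files hold whole-number read counts per annotated gene, not normalised, for 17558 genes in each library. Per the submitters' processing notes, the authors used Trimmomatic, STAR, bedtools and DESeq and the genome builds BDGP6 and mm10. Their roles, versions and settings are not given in the sources used here. The gene coordinates in the files are fly coordinates on BDGP6, and what mm10, a mouse build, was used for is not given. Coordinates are printed from 1. Of the gene identifiers, 17252 were found in release 115 of the fly annotation and 16977 had identical start and end positions there. The symbols are those of the deposited files.

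Each count covers a whole gene span, introns included. Overlapping spans are common, since 8335 genes (47.5%) overlap another gene and 6374 overlap one on the opposite strand. Whether reads were counted by strand was checked on genes that lie inside another gene. The inner gene never had more counts than its host in 1601 of 1623 pairs on opposite strands and in 1242 of 1242 pairs on the same strand with at least 100 counts. Where the inner gene covered at least 80% of its host on the opposite strand (20 pairs), its counts were a median 0.955 of the host's. Reads from both strands therefore entered both genes of an overlapping pair. A gene with an abundant overlapping partner is uncertain, and the partner is named in the text with its count as a multiple of the gene's own. The transgene itself is not among the genes counted, so its expression is not analysed here. GC content was not used here because no genome sequence was at hand.

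Library totals ran from 11452337 counts in Chrom2-5R replicate 1 to 53615117 in Chrom3-5R replicate 4. Levels are scaled to library size as CPM. A gene at 1 CPM has 11.5 counts in the shallowest library and 53.6 in the deepest, and counting error weighs most on low genes in the chromosome 2 libraries. The 10 most abundant genes took 3.28% to 5.74% of a library, ribosomal RNA genes 0.141% to 0.27%, and mitochondrial genes 0.668% to 0.965%. Within each group every pair of libraries differed beyond sampling noise (chi-square per degree of freedom 6.91 to 43.66), so no library was counted as a copy of another. The labels do not say whether replicates came from separate crosses or collections. The p-values measure the spread between these libraries, which may be technical.

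Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr, which kept 13525 genes. Libraries were scaled with TMM factors, and all 16 libraries were fitted together as 4 group means with robust quasi-likelihood dispersions (glmQLFit, glmQLFTest). The biological coefficient of variation was 0.106. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. The contrasts were 160R minus 5R on chromosome 2, 160R minus 5R on chromosome 3, the mean of both, the chromosome 3 change minus the chromosome 2 change, and Chrom3-5R minus Chrom2-5R. Genes called with the same sign on both chromosomes were compared with the overlap of independent lists by one-sided Fisher's exact tests. Changes are log2 fold changes with standard errors (SE), and levels are TMM-scaled CPM as mean ± SD over 4 libraries.

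Lists of genes fixed before the data were examined (31) covered heat shock proteins and chaperones, nucleocytoplasmic transport, ALS and FTD gene orthologs, RNA-binding and splicing proteins, antimicrobial peptides and Toll or Imd targets, Turandot and JAK-STAT targets, cell death and DNA damage, the unfolded protein and integrated stress response, oxidative stress and detoxification, autophagy and lysosome, synaptic and neuronal markers, glial markers, photoreceptor and phototransduction genes, fat body markers, muscle markers, hemocyte markers, midgut digestive enzymes, male germline and accessory gland genes, female markers, male dosage compensation RNAs, the circadian clock, neuropeptides, activity-regulated genes, eye and body colour marker genes, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, the proteasome, mitochondrially encoded genes, spliceosomal small nuclear RNAs, small nucleolar and Cajal body RNAs, and histones. Lists with at least 3 measured members (30, histones left out with 1 measured) were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and p-values were adjusted over the 30 lists. The same test with a correlation estimated per list, and fry from the same package, were run as alternatives. With an estimated correlation, camera called 0 of the 30 lists in each of the 5 comparisons (2, 4, 3, 0 and 3 lists at an unadjusted p below 0.05), so every list call rests on the preset correlation. In the same order fry called 12, 0, 12, 1 and 12 lists (16, 9, 15, 5 and 13 unadjusted). A list of cuticle and chitin genes, one of larval serum protein and larval fat body genes and one of indirect flight muscle genes were added after the data were seen, with p-values adjusted over these 3.

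Genes named in the text follow a rule fixed before the data were examined. Among called genes whose libraries did not overlap between the groups compared and whose mean log2 CPM was at least 0, it takes the 8 largest rises and the 8 largest falls of a comparison. From each list it takes up to 3 called members with the smallest p. It also takes the 10 strongest genes shared by both chromosomes, the 5 strongest differences between chromosomes, and always w, y, v, roX1, roX2, elav and Yp1. Where a list had 5 or fewer calls in a direction, members outside the rule are named too, and these were chosen after their values were seen. The largest rises and falls are all named, but the text names only a part of the list members that the rule takes, and that part was chosen after their values were seen. Some members of these lists are not reported here.

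The alternatives were RLE and upper-quartile scaling, no filter on low counts and a stricter filter (mean CPM of at least 5), DESeq2 1.42.0, limma-voom, fits of only the groups compared, structural RNA genes left out, the replicate number as a block, each library left out in turn, and a fold change of at least 1.5. Chosen after the data were seen were a test of only genes that overlap no other gene, a test with all libraries thinned to the smallest total, and a test without Chrom2-160R replicate 1 and Chrom3-160R replicate 4, the libraries of their groups highest in cuticle genes. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

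The fit was tested on simulated counts drawn from each gene's mean over all 16 libraries and the real library sizes (13460 genes). In these, 50 genes were changed at each of 4 sizes of fold change. At a 1.25-fold change the fit recovered 46% of the changed genes in the chromosome 2 comparison, 66% on chromosome 3, 72% in the mean of both, 14% in the difference between chromosomes, and 42% between the 5R lines. At a 1.5-fold change it recovered 84%, 84%, 92%, 68% and 84% of them, in the same order. False calls made up 3.4% to 5.9% of all calls. The real differences between groups were not simulated, so these rates may not hold for the real data.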

Results

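Gene expression was compared between heads of flies expressing the long (160R) and the short (5R) repeat, separately for transgenes on chromosome 2 and chromosome 3. The 4 groups held 4 libraries each. Total counts per library were 11452337 to 23498476 in Chrom2-5R, 19047916 to 30496479 in Chrom2-160R, 42854987 to 53615117 in Chrom3-5R and 48118158 to 49792428 in Chrom3-160R. The chromosome 3 libraries held 3.74 to 4.68 times the counts of the smallest library and the chromosome 2 libraries 1.0 to 2.66 times, so insertion line and depth go together. In a principal component analysis of log2 CPM over the 16 libraries, the second component (23.8% of variance) parted the chromosome 2 libraries (10.5 to 31.8) from the chromosome 3 libraries (-20.1 to -15.3). The leading component (25.2%) was 13.7 to 45.5 in Chrom2-160R and -28.3 to -13 in Chrom2-5R. It was -1.9 to 19.6 in Chrom3-160R and -16.9 to 0.7 in Chrom3-5R. Chrom2-160R replicate 1, at 45.5, and Chrom3-160R replicate 4, at 19.6, were the highest of their groups. Gene levels below are CPM as mean ± SD over 4 libraries, and a fold change stands with its SE.

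In flies carrying the transgene on chromosome 2, cytosolic ribosomal protein, fat body and detoxification genes were called lower as lists in 160R heads than in 5R heads, and synaptic, mitochondrial ribosomal protein and muscle genes higher. With an estimated correlation these calls were lost (camera adjusted p = 0.614, 0.327, 0.614, 0.614, 0.688 and 0.688, in the same order), and the muscle call was also lost without Chrom2-160R replicate 1 (0.11, within a range of 0.0015 to 0.688). Hsp23, a small heat shock protein, rose from 13.6 ± 1.34 to 61.4 ± 26.2 CPM, a log2 change of 2.17 ± 0.31 (edgeR adjusted p = 0.00034). Rfabg, the lipoprotein precursor made in the fat body and among the most abundant transcripts of the head, fell from 9080 ± 688 to 5740 ± 412 CPM. In all, 3535 of 13525 genes were called (26.1%), 1735 higher and 1800 lower, and 738 of them changed by at least 1.5-fold. The comparison sets 160R against 5R flies with the transgene on this chromosome. Here and on chromosome 3, 160R and 5R flies may also differ in genetic background or batch. The labels do not give these, so they cannot be told apart from the repeat.

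Most of the largest rises were in genes with a low level in 5R flies and a wide spread in 160R flies. CG7214 (2L, 7743682 to 7744839), an uncharacterised gene, went from 2.85 ± 3.39 to 214 ± 141 CPM, a log2 change of 6.07 ± 1.55 (edgeR adjusted p = 0.013). Its neighbour CG7203 (2L, 7752170 to 7753186) rose by 4.02 ± 0.99 on the log2 scale (edgeR adjusted p = 0.011). Acp1 (2L, 7740562 to 7741537), an adult cuticle protein, rose by 5.54 ± 1.7 and CG8736 by 4.9 ± 1.5 (edgeR adjusted p = 0.03 for both). The Acp1 call ended without any 1 of the Chrom2-5R libraries (edgeR adjusted p 0.0523 to 0.0817) or without Chrom2-160R replicate 1 (0.0946), and ranged from 0.0178 to 0.172 over its alternatives. The CG8736 call ended without Chrom2-5R replicate 1, 2 or 3 (0.0729 to 0.0813 by edgeR) or Chrom2-160R replicate 1 (0.108), within a range of 0.0215 to 0.128. Limma-voom did not call CG7214 (adjusted p = 0.062), whose range over alternatives was 1.13e-06 to 0.062. The other 4 of the 8 largest rises were CG34327 (4.41 ± 1.36), CG13056 (4.4 ± 1.49), CG16884 (4.03 ± 1.27), whose partner Ance-3 has 5.83 times its counts, and CG11458 (3.92 ± 1; edgeR adjusted p = 0.032, 0.046, 0.035 and 0.013). The calls of CG34327, CG13056 and CG16884 ended without any 1 of the Chrom2-5R libraries or without Chrom2-160R replicate 1 (edgeR adjusted p 0.0572 to 0.119, 0.0919 to 0.209 and 0.0593 to 0.17), within ranges of 0.0233 to 0.16, 0.000594 to 0.245 and 0.0199 to 0.172. Limma-voom called none of these 4 (CG11458 at an adjusted p of 0.0922, in a range from 2.3e-06).

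The largest falls were tighter. CG18673 (3R, 31262598 to 31263878), of the carbonic anhydrase family, dropped from 12.6 ± 3.04 to 0.906 ± 0.082 CPM, a log2 change of -3.82 ± 0.41 (edgeR adjusted p = 3.1e-05). CG33926 changed by -2.54 ± 0.45 and CG10924, a phosphoenolpyruvate carboxykinase, by -2.14 ± 0.41 (edgeR adjusted p = 0.0014 and 0.0023). CG8665, a folate enzyme (2L, 21371227 to 21377995), fell from 197 ± 65.8 to 45.9 ± 6.4 CPM, a log2 change of -2.1 ± 0.23 (edgeR adjusted p = 4.8e-05). CG12256 and CG15120 changed by -2.08 ± 0.35 and -2.0 ± 0.24, but both overlap other genes (CR43477 with 0.94 and CG16926 with 20.1 times their counts) and are uncertain. CR43477 itself changed by -2.07 ± 0.35 and Ugt37b1 by -1.75 ± 0.35 (edgeR adjusted p = 0.00087 and 0.0018).

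Of the 84 cytosolic ribosomal protein genes measured, 76 fell and none rose (79 and 0 adjusted over the list alone), with a median log2 change of -0.35. The list was lower by camera (adjusted p = 9.59e-25, and adjusted p = 0.614 with an estimated correlation). Its median in centred log2 CPM was 0.18 to 0.56 in Chrom2-5R and -0.07 to 0.15 in Chrom2-160R. In the chromosome 3 libraries it was -0.28 to -0.07. Over the 4 groups the medians fell as mean library totals rose. Chrom2-5R, the control, stood highest, so the fall cannot be put down to the repeat alone. RpS24 changed by -0.47 ± 0.06, RpLP0 by -0.45 ± 0.06 and RpL37a by -0.5 ± 0.07. Many of these genes host small RNA genes, and 46 of the 84 overlap another gene. Mitochondrial ribosomal proteins were called higher as a list with the preset correlation. Of 73 measured, 19 rose and 2 fell (21 and 2 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.00052, and adjusted p = 0.688 with an estimated correlation). Among them mRpL23 rose by 0.46 ± 0.1, although its partner CG8993 has 2.21 times its counts. The falls were mRpL37 (-0.48 ± 0.06) and mRpS28 (-0.63 ± 0.09).

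Fat body markers were called lower as a list with the preset correlation. Of 18 measured, 10 fell and none rose (11 and 1 adjusted over the list alone), and the median was -0.68 (camera adjusted p = 0.000141, and adjusted p = 0.327 with an estimated correlation). Rfabg changed by -0.66 ± 0.06, Mtp, the microsomal triglyceride transfer protein, by -0.77 ± 0.08, and ACC, the acetyl-CoA carboxylase of fatty acid synthesis, by -0.52 ± 0.08 (edgeR adjusted p = 1.5e-06, 5.1e-06 and 0.00026). Of 31 oxidative stress and detoxification genes, 13 fell and 1, Cyp6a2, rose (14 and 1 adjusted over the list alone), with a median of -0.2 (camera adjusted p = 0.00955, and adjusted p = 0.614 with an estimated correlation). The glutathione S-transferase genes GstE9 and GstE3 changed by -0.79 ± 0.06 and -0.62 ± 0.1, and the cytochrome P450 Cyp6a8 by -1.71 ± 0.24. Of 19 genes of the unfolded protein and integrated stress response, 9 fell and none rose (10 and 1 adjusted over the list alone), the median being -0.12 (camera adjusted p = 0.0272, and adjusted p = 0.614 with an estimated correlation). PEK, the kinase that senses endoplasmic reticulum stress, changed by -0.27 ± 0.04, the calreticulin gene Crc by -0.24 ± 0.05 and crc, the ATF4 transcription factor, by -0.23 ± 0.05. This list call ended without Chrom2-5R replicate 1 (camera adjusted p = 0.0697), Chrom2-5R replicate 4 (0.0631) or Chrom2-160R replicate 1 (0.0802), and with the stricter filter (0.057), within a range of 0.00426 to 0.614 over its alternatives.

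Synaptic and neuronal markers were higher, with 11 of 24 called up and 1 down (16 and 2 adjusted over the list alone) and a median of 0.15 (camera adjusted p = 0.00052, and adjusted p = 0.614 with an estimated correlation). Gad1, which makes the transmitter GABA, rose by 0.41 ± 0.06 and the dopamine transporter DAT by 0.38 ± 0.06, while Rbp9, a neuronal RNA-binding protein, changed by -0.52 ± 0.04. Muscle markers rose in 9 of 21 and fell in none (12 and 1 adjusted over the list alone), with a median of 0.4 (camera adjusted p = 0.00955, and adjusted p = 0.688 with an estimated correlation). The troponin T gene up changed by 0.99 ± 0.24, the tropomyosin gene Tm1 by 0.58 ± 0.16 and TpnC25D by 1.1 ± 0.27, the last with an overlapping partner, tkv, at 2.96 times its counts. The muscle list's median in centred log2 CPM was 0.97 in Chrom2-160R replicate 1 and 0.14 to 0.21 in the other Chrom2-160R libraries. Without that library the muscle list was not called (camera adjusted p = 0.11, within a range of 0.0015 to 0.688 over its alternatives), and without it and Chrom3-160R replicate 4 the list's median change was 0.19. A list of cuticle and chitin genes chosen after the data were seen had 17 of 88 higher and 1, Edg78E, lower (16 and 1 adjusted over the list alone; median 0.34; camera adjusted p = 0.00391, and adjusted p = 0.703 with an estimated correlation). Its centred median was 0.5 in Chrom2-160R replicate 1 and -0.02 to 0.13 in the other Chrom2-160R libraries, and without that library and Chrom3-160R replicate 4 its median change was 0.21.

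**Figure D1:**
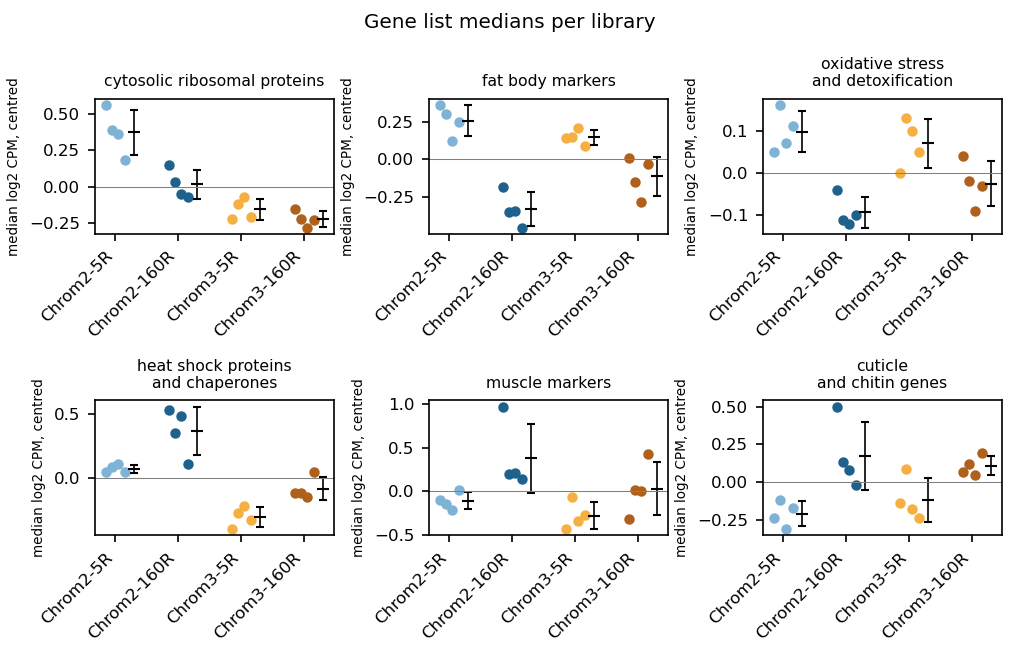
Median log2 CPM of 6 gene lists in each library, centred on the mean of the 16 libraries (vertical axes), by group (horizontal axes). Points are libraries and bars the mean ± SD of 4 libraries. The cuticle list was chosen after the data were seen. In the muscle panel Chrom2-160R replicate 1 lies at 0.97 and the other Chrom2-160R libraries at 0.14 to 0.21.

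The remaining lists were not called on chromosome 2. Heat shock proteins and chaperones went both ways, with 7 of 21 higher, among them Hsp67Bc (0.68 ± 0.09), and 3 lower (7 and 3 adjusted over the list alone). The falls were DnaJ-1 (-0.59 ± 0.06), Hsc70-4 and Hsp83, and the list's median was 0.24 (camera adjusted p = 0.275). Nucleocytoplasmic transport genes, a class studied in C9ORF72 models, were lower in 7 of 33 and higher in 1, CG14749 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0694). ALS and FTD gene orthologs fell in 5 of 20, among them ref(2)P and Atx2, and rose in 1, Pur-alpha (5 and 2 adjusted over the list alone; camera adjusted p = 0.316). ref(2)P, the p62 ortholog, changed by -0.44 ± 0.04. RNA-binding and splicing proteins rose in 3 of 34 (how, nonA and Pur-alpha) and fell in 4, among them rump and U2af38 (the same counts adjusted over the list alone; camera adjusted p = 0.97). CG14749 was lost without Chrom2-5R replicate 3 (edgeR adjusted p = 0.0588, in a range from 0.00605 to 0.076). Atx2 was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.13) or 3 (0.0726) or Chrom2-160R replicate 1 (0.0783) or 2 (0.129), in a range from 0.0217 to 0.141. U2af38 was lost without Chrom2-5R replicate 2 (edgeR adjusted p = 0.115) or 3 (0.0684) or Chrom2-160R replicate 1 (0.0745) or 3 (0.0712), in a range from 0.0147 to 0.115.

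No immune list was called. Antimicrobial peptide and Toll or Imd genes rose in 6 of 33, among them IM2 (0.73 ± 0.14) and IM23 (1.1 ± 0.22), and fell in 1, CG16712 (camera adjusted p = 0.261). Turandot and JAK-STAT genes rose in 1 of 11, the cytokine upd3 (1.26 ± 0.28), and fell in 1, Stat92E (-0.35 ± 0.03; camera adjusted p = 0.706). Hemocyte markers rose in 2 of 13 (Cg25C and vkg) and fell in 2 (Nplp2 and srp; camera adjusted p = 0.909). Cell death and DNA damage genes rose in 2 of 23 (Ku80 and skl) and fell in 4 (lok, Xrp1, tefu and rad50; camera adjusted p = 0.909). Autophagy and lysosome genes fell in 7 of 24 and rose in 1, Atg1 (camera adjusted p = 0.269). Adjusted over the list alone these 5 lists gave the same counts, except 2 higher and 7 lower for autophagy. CG16712 was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.0529, in a range from 0.00222 to 0.0529) and skl without Chrom2-5R replicate 3 (0.0693) or 4 (0.0559), in a range from 0.00843 to 0.0693. Also lost were tefu without any 1 of the 8 chromosome 2 libraries except Chrom2-5R replicate 2 and Chrom2-160R replicate 2 (edgeR adjusted p 0.0573 to 0.135, in a range from 0.0164 to 0.165), and rad50 without any except Chrom2-5R replicate 2 and Chrom2-160R replicate 4 (0.0517 to 0.14, in a range from 0.0278 to 0.14).

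Among cell type and clock lists, glial markers rose in 8 of 17 and fell in 1, SP2637 (camera adjusted p = 0.112), and photoreceptor genes rose in 9 of 29 and fell in 7 (0.643 by camera). Circadian genes rose in 3 of 12 (nmo, cwo and Pdp1) and fell in 3 (camera adjusted p = 0.542). The falls were the blue-light receptor cry (-0.64 ± 0.07; its partner vib has 0.92 times its counts), to, a secreted protein under clock control (-1.41 ± 0.3), and the clock neuropeptide Pdf (-0.3 ± 0.07). Neuropeptides rose in 3 of 26 (Ilp3, Tk and Proc) and fell in 8, among them Mip (-0.44 ± 0.06; camera adjusted p = 0.266). Ilp3 rose by 0.89 ± 0.08 but its partner CG32052 has 8.55 times its counts. Activity-regulated genes fell in 2 of 10 (kay and Arc1; camera adjusted p = 0.294). Midgut digestive enzymes fell in 3 of 7, namely the amylase genes Amy-d (-1.35 ± 0.15) and Amy-p and LM408, a lysosomal mannosidase gene (-0.95 ± 0.07), and rose in 1, Mal-A7 (camera adjusted p = 0.105). Adjusted over the list alone the counts were the same, except 8 lower for photoreceptor genes, 4 lower for circadian genes and 4 higher for neuropeptides. SP2637 was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.0742) or 2 (0.0513) or Chrom2-160R replicate 4 (0.0649), in a range from 0.00777 to 0.219. Pdp1 was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.0651), 2 (0.0677) or 3 (0.0612) or Chrom2-160R replicate 2 (0.0693), in a range from 0.00246 to 0.0693. Proc was lost without Chrom2-5R replicate 2 (edgeR adjusted p = 0.0633) or Chrom2-160R replicate 3 (0.067) or 4 (0.0636), in a range from 0.00706 to 0.113. Mal-A7 was lost without any 1 of the 8 chromosome 2 libraries except Chrom2-5R replicate 3 and Chrom2-160R replicates 3 and 4 (edgeR adjusted p 0.0524 to 0.1, in a range from 0.0159 to 0.1).

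Male germline and accessory gland genes rose in 1 of 8 (camera adjusted p = 0.261). The gene was Peb, a protein of the ejaculatory bulb, which stood at 27.1 ± 48.6 CPM in Chrom2-160R and 0.204 ± 0.147 in Chrom2-5R, and limma-voom did not call it (adjusted p = 0.304, within a range of 4.2e-08 to 0.304). That list's median was 2.05 in Chrom2-160R replicate 1 and -0.02 to 0.25 in the others of the group. Female markers fell in 2 of 6 (Yp3 and Yp1; camera adjusted p = 0.261), dosage compensation RNAs in 2 of 3 (msl-2 and roX1; 0.303 by camera). Colour marker genes rose in 3 of 7 (w, bw and y) and fell in 2 (v and ry; camera adjusted p = 0.706). Spliceosomal small nuclear RNAs fell in 3 of 16 (snRNA:U11, snRNA:U5:63BC and snRNA:U4:39B; camera adjusted p = 0.147), small nucleolar RNAs rose in 14 of 213 and fell in 12 (0.68 by camera), mitochondrially encoded genes rose in 1 of 37, mt:ND4 (0.316), and proteasome genes in 0 of 31 (0.95). Adjusted over the list alone the counts were the same, except 1 lower for small nuclear RNAs, 7 higher and 9 lower for small nucleolar RNAs and 0 for mitochondrially encoded genes. The msl-2 call was lost without Chrom2-5R replicate 2 (edgeR adjusted p = 0.0632) or 3 (0.0535), in a range from 0.00649 to 0.132, and mt:ND4 without Chrom2-5R replicate 3 (0.0644) or 4 (0.0605) or Chrom2-160R replicate 1 (0.0876) or 2 (0.1), in a range from 0.0076 to 0.127. The snRNA:U4:39B call was lost without any 1 of the 8 chromosome 2 libraries except Chrom2-160R replicate 3 (edgeR adjusted p 0.0503 to 0.121, in a range from 0.00587 to 0.121), and snRNA:U5:63BC without any except Chrom2-5R replicates 2 and 3 and Chrom2-160R replicate 4 (0.0671 to 0.236, in a range from 0.0213 to 0.236). The members w, y, v, roX1 and Yp1 are given at the end.

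Upper-quartile scaling split the chromosome 2 calls 2399 higher and 1274 lower (65.3% higher, against 49.1% with TMM), so the balance of directions depends on scaling. A fit of the chromosome 2 libraries alone called 2293 genes, and a fit of the genes that overlap no other gene called 1720. Without the 2 libraries highest in cuticle genes the count was 3281.

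**Figure D2:**
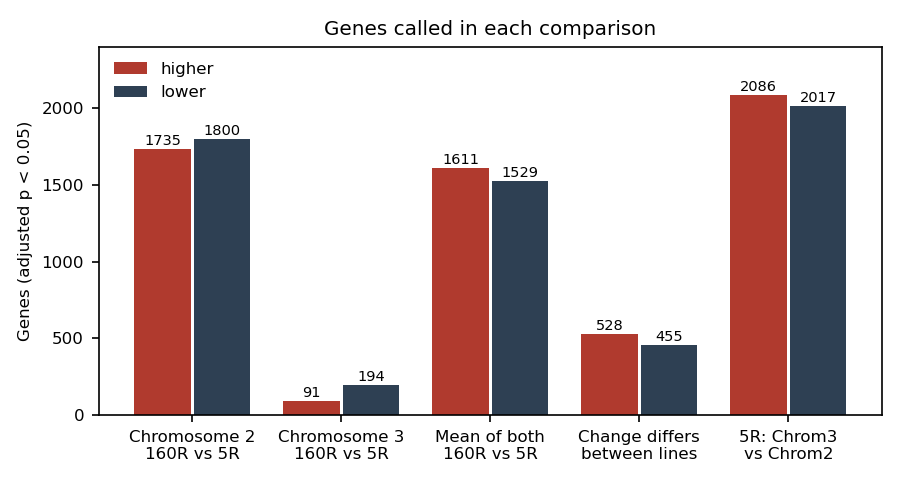
Number of genes called (vertical axis, edgeR adjusted p below 0.05) in each of the 5 comparisons (horizontal axis), split into higher and lower. Bars are counts out of 13525 genes tested. The chromosome 2 comparison gave 1735 higher and 1800 lower, the chromosome 3 comparison 91 and 194.

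On chromosome 3, 160R and 5R heads differed in fewer genes, 285 in all (2.1%), of which 91 were higher and 194 lower. The clearest change was a rise of the cytochrome P450 gene Cyp28d2 (2L, 5207267 to 5209345), from 7.39 ± 1.05 to 79.1 ± 3.83 CPM. Its log2 change was 3.42 ± 0.08 (edgeR adjusted p = 5.2e-15), and it was higher in all 4 of the 160R libraries than in any 5R library. Detoxification and fat body genes were called lower as lists and muscle genes higher, but these calls were lost with an estimated correlation (camera adjusted p = 0.336, 0.336 and 0.633). Few of their members passed on their own, 2 of 31 detoxification genes (lower), 2 of 18 fat body genes (1 lower and 1 higher) and 0 of 21 muscle genes. At an unadjusted p below 0.05, 1986 genes differed.

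Other rises were CG11313 (3R, 30729837 to 30731165), an uncharacterised gene, from 23.2 ± 5.09 to 53 ± 6.05 CPM, a log2 change of 1.19 ± 0.16 (edgeR adjusted p = 0.00096). CG34215 rose by 1.26 ± 0.12 and Cyp4p2 by 1.12 ± 0.1, with overlapping partners at 6.43 (CG15236) and 39.1 times (hig) their counts, so both are uncertain. Among the falls, CG14238 (3R, 26458249 to 26460981) went from 9.92 ± 0.855 to 1.15 ± 0.405 CPM, a log2 change of -3.1 ± 0.18 (edgeR adjusted p = 1.5e-08). Unc-115b and p24-2, which overlap on 3R (9687060 to 9692794) and cannot be told apart by counts, changed by -2.94 ± 0.19 and -2.9 ± 0.19. CG42876 changed by -1.88 ± 0.13 and CG8757 by -1.77 ± 0.2 (edgeR adjusted p = 2.1e-07 and 4.6e-05). The P450 gene Cyp9c1 changed by -1.75 ± 0.09 and CR43787, which overlaps it, by -1.74 ± 0.08, with a further partner, CG13594, at 5.41 times the counts of Cyp9c1. The 8 largest rises also held CR44043 (1.23 ± 0.13), with l(2)41Ab at 33.8 times its counts, CG6280 (1.03 ± 0.18), CG3987 (0.93 ± 0.21), with CR45600 at 4.51 times its counts, and CG32368 (0.91 ± 0.22), and the 8 largest falls CR44602 (-1.56 ± 0.22). Their edgeR adjusted p were 3.2e-05, 0.0035, 0.033, 0.042 and 0.00049. CG3987 was lost without any 1 of the 8 chromosome 3 libraries except Chrom3-5R replicate 4 (edgeR adjusted p 0.0534 to 0.115, in a range from 0.000734) and CG32368 without any except Chrom3-160R replicates 1 and 4 (0.0657 to 0.156, in a range from 0.00797).

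**Figure D3:**
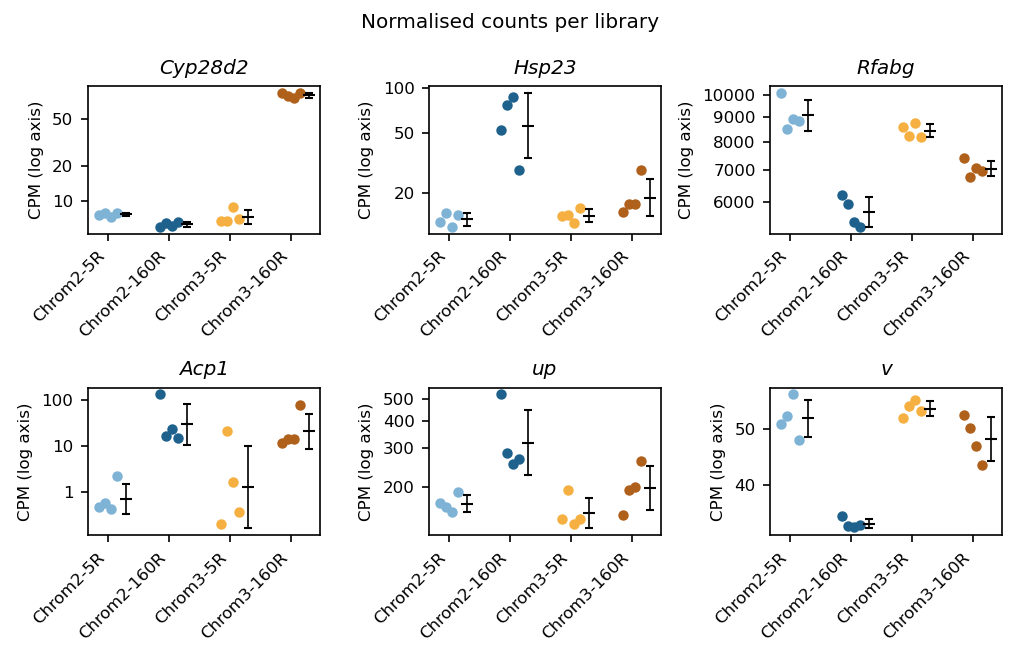
CPM of 6 genes in each library (vertical axes, log scale) by group (horizontal axes). Points are libraries and bars the geometric mean with the SD of log2 CPM over 4 libraries. Cyp28d2 stands at 79.1 CPM in Chrom3-160R and at 6.35 to 7.69 CPM in the other groups.

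Of the 30 lists, camera called 12 on chromosome 3, mostly with few called members, and the rotation test fry called 0 (9 at an unadjusted p below 0.05). Of 31 oxidative stress and detoxification genes 2 fell, GstE9 (-0.32 ± 0.06) and GstD3 (-0.3 ± 0.07), and none rose (8 and 0 adjusted over the list alone), the median being -0.11 (camera adjusted p = 0.00194, and adjusted p = 0.336 with an estimated correlation). Fat body markers had a median of -0.27, with Rfabg lower (-0.26 ± 0.06) and Obp99a, an odorant-binding protein, higher (1.59 ± 0.31) among 18 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.336 with an estimated correlation). Of 19 unfolded protein response genes Crc (-0.2 ± 0.05) and Pdi (-0.22 ± 0.05), both chaperones of the endoplasmic reticulum, fell (5 adjusted over the list alone; camera adjusted p = 0.00266, and adjusted p = 0.378 with an estimated correlation). Midgut enzymes fell in 1 of 7, Amy-d (-0.64 ± 0.14; 3 adjusted over the list alone; camera adjusted p = 0.00454, and adjusted p = 0.336 with an estimated correlation). RNA-binding proteins fell in 1 of 34, bru-3 (-0.24 ± 0.06; 1 adjusted over the list alone; camera adjusted p = 0.00241, and adjusted p = 0.378 with an estimated correlation). Small nucleolar RNAs fell in 1 of 213, snoRNA:Psi18S-525c (0 adjusted over the list alone; camera adjusted p = 0.0179, and adjusted p = 0.637 with an estimated correlation), and this list call ended without Chrom3-5R replicate 3 (0.47) or Chrom3-160R replicate 1 (0.123) and ranged from 6.65e-05 to 0.637 over its alternatives.

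Nucleocytoplasmic transport genes were lower by camera with 0 of 33 members called (0 adjusted over the list alone; median -0.05; adjusted p = 0.00425, and adjusted p = 0.336 with an estimated correlation), as were cytosolic ribosomal proteins with 0 of 84 (0 adjusted over the list alone; median -0.06; camera adjusted p = 0.00061, and adjusted p = 0.892 with an estimated correlation). After thinning, the transport list was not called (camera adjusted p = 0.0852, within a range of 0.00212 to 0.336). Higher lists were muscle markers with 0 of 21 called (0 adjusted over the list alone; median 0.35; camera adjusted p = 0.000517, and adjusted p = 0.633 with an estimated correlation) and mitochondrial ribosomal proteins with 1 of 73, mRpL39 (0.28 ± 0.05; 1 adjusted over the list alone; camera adjusted p = 0.000257, and adjusted p = 0.633 with an estimated correlation). Glial markers were higher with 1 of 17 called, alrm (0.31 ± 0.08; 1 adjusted over the list alone; camera adjusted p = 0.00194, and adjusted p = 0.378 with an estimated correlation). Photoreceptor genes were higher with 1 of 29, rdgC (0.14 ± 0.03; 2 adjusted over the list alone; camera adjusted p = 0.00206, and adjusted p = 0.378 with an estimated correlation). The muscle list's median in centred log2 CPM was 0.43 in Chrom3-160R replicate 4 and -0.32 to 0.02 in the other Chrom3-160R libraries, and without that library and Chrom2-160R replicate 1 its median change was 0.21. The partner Fur1 has 5.05 times the counts of alrm and Zip71B 1.03 times those of mRpL39. Outside the called lists, the neuropeptide genes Dh31 (-0.28 ± 0.04) and ITP (-0.33 ± 0.06) fell and Pi3K59F, of the autophagy list, rose (0.22 ± 0.04). Heat shock genes were called in 0 of 21 (3 higher adjusted over the list alone; camera adjusted p = 0.161).

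Several of these calls depended on 1 library. GstD3 and rdgC were lost without any 1 of the 8 chromosome 3 libraries (edgeR adjusted p 0.0549 to 0.127 and 0.0886 to 0.173). bru-3 was lost without any except Chrom3-5R replicate 2 (0.0511 to 0.144 by edgeR), Crc without any except Chrom3-5R replicate 4 and Chrom3-160R replicate 1 (0.066 to 0.139), and Rfabg without any except Chrom3-5R replicate 2 and Chrom3-160R replicate 1 (0.0558 to 0.111). Pdi was lost without Chrom3-5R replicate 1, 2 or 3 or Chrom3-160R replicate 2 or 3 (edgeR adjusted p 0.0727 to 0.137), alrm without Chrom3-5R replicate 1 or 3 or Chrom3-160R replicate 2, 3 or 4 (0.0977 to 0.167), and Amy-d without Chrom3-5R replicate 2 or 3 or Chrom3-160R replicate 2, 3 or 4 (0.0562 to 0.107). The snoRNA:Psi18S-525c call (-0.74 ± 0.18) was lost without any except Chrom3-5R replicates 1 and 2 (edgeR adjusted p 0.0699 to 0.152), and its partner Arpc2 has 28.5 times its counts. Over their alternatives the highest edgeR adjusted p of these 9 genes was 0.111 (Rfabg) to 0.191 (GstD3) and the lowest 0.000302 (Amy-d) to 0.00875 (alrm). The count of 285 fell to 176 and 167 without Chrom3-5R replicates 1 and 3 and to 181 and 170 without Chrom3-160R replicates 2 and 3. DESeq2 called 523 genes, thinning to the smallest total left 140, and a fit of the genes that overlap no other gene called 144.

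Averaged over both chromosomes, fat body, detoxification and cytosolic ribosomal protein genes were called lower as lists in 160R heads, and muscle, glial and mitochondrial ribosomal protein genes higher. These calls were lost with an estimated correlation (camera adjusted p = 0.268, 0.369, 0.477, 0.609, 0.477 and 0.605, in the same order). Hsp26, a small heat shock protein, rose by 1.45 ± 0.28 on the log2 scale (edgeR adjusted p = 0.0033), ninaD, a carotenoid receptor, by 1.05 ± 0.15 (edgeR adjusted p = 0.0003), and Lsp1beta, a larval serum protein, changed by -1.33 ± 0.23 (edgeR adjusted p = 0.0015). In all 3140 genes were called, 1611 higher and 1529 lower, 390 of them at 1.5-fold or more, and for 388 the libraries did not overlap within either chromosome. Upper-quartile scaling split the calls 2036 and 1195 (63% higher, against 51.3%).

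The other large rises included Cpr76Bd, a cuticle protein gene (2.76 ± 0.74; edgeR adjusted p = 0.018), CG10936 (1.06 ± 0.2; 0.0031) and NimC4, a receptor for apoptotic corpses (1.71 ± 0.36; 0.005), whose partner nAChRalpha5 has 43.2 times its counts. Limma-voom did not call Cpr76Bd (adjusted p = 0.0881, within a range of 0.000283 to 0.0881). Large falls included CG42876 (-1.5 ± 0.11; edgeR adjusted p = 2.9e-07), Obp99b, an odorant-binding protein (-1.31 ± 0.25; 0.0027), CG1979 (-1.19 ± 0.13; 2.4e-05) and the P450 gene Cyp309a1 (-1.13 ± 0.23; 0.0038). The 8 largest rises also held CG13056 (3.53 ± 0.9; edgeR adjusted p = 0.014), CR44043 (2.08 ± 0.11; 6e-09), with l(2)41Ab at 33.8 times its counts, and CG13183 (1.2 ± 0.39; 0.04). The 8 largest falls also held Ugt37b1 (-1.28 ± 0.2; edgeR adjusted p = 0.00036), CG8665 (-1.25 ± 0.16; 0.00017) and CG18446 (-1.08 ± 0.08; 3.8e-07), with cbx at 9.99 times its counts. Limma-voom did not call CG13056 (adjusted p = 0.0722, in a range from 4.19e-05). CG13183 was lost without any 1 of the 8 libraries of 5R flies, Chrom2-160R replicate 1 or Chrom3-160R replicate 4 (edgeR adjusted p 0.0543 to 0.0818, in a range from 0.003 to 0.0889). Victoria, of the Turandot list (-0.79 ± 0.26; edgeR adjusted p = 0.037), has a partner, sick, at 723 times its counts. It was lost without Chrom2-5R replicate 1, 2 or 3, Chrom2-160R replicate 2 or 4, Chrom3-5R replicate 2 or 3 or Chrom3-160R replicate 1 or 4 (edgeR adjusted p 0.0518 to 0.106, in a range from 0.00854).

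On the mean, 10 of the 30 lists were called. Cytosolic ribosomal proteins fell in 71 of 84 (75 adjusted over the list alone; median -0.21; camera adjusted p = 5.1e-22, and adjusted p = 0.477 with an estimated correlation) and mitochondrial ribosomal proteins rose in 16 of 73 and fell in 2, mRpL37 and mRpS28 (32 and 2 adjusted over the list alone; median 0.11; camera adjusted p = 1.63e-05, and adjusted p = 0.605 with an estimated correlation). For the cytosolic list the median change was -0.35 on chromosome 2 and -0.06 on chromosome 3, and Chrom2-5R stood highest of the groups. Fat body markers fell in 12 of 18 and rose in 1, Fbp1, a receptor of larval serum proteins (13 and 2 adjusted over the list alone; median -0.45; camera adjusted p = 4.44e-05, and adjusted p = 0.268 with an estimated correlation). Detoxification genes fell in 14 of 31 and rose in 2, Cyp6a2 and Sod2 (14 and 2 adjusted over the list alone; median -0.16; camera adjusted p = 0.00149, and adjusted p = 0.369 with an estimated correlation). Muscle markers rose in 13 of 21 (13 adjusted over the list alone; median 0.33; camera adjusted p = 0.000398, and adjusted p = 0.609 with an estimated correlation). Glial markers rose in 9 of 17, among them alrm (0.33; edgeR adjusted p = 0.00046), and fell in 1, SP2637 (9 and 1 adjusted over the list alone; median 0.12; camera adjusted p = 0.0108, and adjusted p = 0.477 with an estimated correlation). The cuticle list chosen after the data were seen rose in 28 of 88 and fell in 1, TwdlG (29 and 2 adjusted over the list alone; camera adjusted p = 4.89e-05, and adjusted p = 0.444 with an estimated correlation), and without Chrom2-160R replicate 1 and Chrom3-160R replicate 4 the counts were 22 for cuticle and 10 for muscle and the medians 0.13 (0.27 with them) and 0.16. Fbp1 was lost without any 1 of the 16 libraries except Chrom2-160R replicates 3 and 4 and Chrom3-160R replicates 1, 2 and 3 (edgeR adjusted p 0.0543 to 0.17, in a range from 0.0362 to 0.269). Sod2 was lost without any except Chrom2-5R replicate 4, the 4 Chrom2-160R libraries and Chrom3-5R replicate 2 (edgeR adjusted p 0.0504 to 0.106, in a range from 0.0166 to 0.17), and Cyp6a2 without Chrom3-5R replicate 1 (0.0545) or Chrom3-160R replicate 2 (0.0528), in a range from 0.00838 to 0.0545. SP2637 was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.0559, in a range from 0.00581 to 0.135) and TwdlG without Chrom2-5R replicate 2 (0.0626) or Chrom2-160R replicate 2 (0.0518), in a range from 0.00599 to 0.0842.

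Nucleocytoplasmic transport genes fell in 11 of 33 and rose in 1, CG14749 (12 and 1 adjusted over the list alone; median -0.06; camera adjusted p = 0.00696, and adjusted p = 0.399 with an estimated correlation). Among them Nup44A changed by -0.22 ± 0.04, with ACC at 26.1 times its counts, and Nup358, a nuclear pore filament protein, by -0.13 ± 0.03. Upper-quartile scaling ended the Nup358 call (edgeR adjusted p = 0.053, within a range of 0.00332 to 0.053). Unfolded protein response genes fell in 6 of 19 (9 and 1 higher adjusted over the list alone; median -0.07; camera adjusted p = 0.00193, and adjusted p = 0.399 with an estimated correlation). Synaptic markers rose in 8 of 24 and fell in 1, Rbp9 (10 and 1 adjusted over the list alone; median 0.05; camera adjusted p = 0.0269, and adjusted p = 0.605 with an estimated correlation), and this call ended without Chrom2-5R replicate 2 (0.0566), Chrom2-160R replicate 2 (0.0521), Chrom3-5R replicate 2 (0.078) or Chrom3-160R replicate 3 (0.0956), in a range from 0.00889 to 0.605. Midgut enzymes fell in 3 of 7, LM408, Amy-d and Amy-p (3 adjusted over the list alone; median -0.1; camera adjusted p = 0.0185, and adjusted p = 0.399 with an estimated correlation). That call ended without Chrom2-5R replicate 1 (camera adjusted p = 0.0656), Chrom2-5R replicate 2 (0.0767) or Chrom2-160R replicate 4 (0.187), in a range from 0.000358 to 0.399. Amy-p was lost without Chrom2-5R replicate 2 (edgeR adjusted p = 0.0544), Chrom2-160R replicate 1 (0.0519) or Chrom3-5R replicate 3 (0.0517), in a range from 0.00426 to 0.0881. CG14749 was lost without any 1 of the 16 libraries except Chrom2-5R replicates 1 and 4, Chrom2-160R replicates 1 and 3 and Chrom3-5R replicate 4 (edgeR adjusted p 0.0522 to 0.099, in a range from 0.0188 to 0.393).

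Genes that changed on both chromosomes were compared next, since a change seen from both insertion sites does not rest on 1 site. In the same direction, 111 genes were called on both, 37 higher and 74 lower. Independent lists would share 11.7 and 25.8 (one-sided Fisher's exact tests, p = 2.64e-11 and 2.07e-18), and no library is common to both contrasts. These tests take genes as independent, although many overlap. Both contrasts also use the dispersions of 1 fit, so the p-values can overstate the overlap. A further 24 genes were called in opposite directions. Over the genes tested, which are not independent replicates, the log2 changes had a Pearson correlation of 0.41 and a Spearman correlation of 0.32, and 190 of the 285 chromosome 3 calls had the same sign on chromosome 2 (66.7%).

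Among the strongest shared genes, ppk13, a subunit of a sodium channel family, rose from 0.172 ± 0.0375 to 1.1 ± 0.246 CPM on chromosome 2 and from 0.234 ± 0.0895 to 1.09 ± 0.0613 on chromosome 3. Its log2 changes were 2.69 ± 0.32 and 2.22 ± 0.22 (edgeR adjusted p = 1.7e-05 and 1.6e-05). Npc2g, of a sterol-binding family, changed by -0.71 and -0.47 and the P450 gene Cyp9b2 by -0.91 and -0.48. CG6426 changed by -0.36 and -0.38 and CG1092 by -0.61 and -0.44. CG31683 (-3.48 and -2.72), CR44043 (2.93 and 1.23), CG18446 (-1.3 and -0.87), Cyp6t3 (-1.13 and -0.9) and CG16965 (-0.65 and -0.5) overlap genes with 3.89 to 112 times their counts and are uncertain. Upper-quartile scaling shared 57 higher and 67 lower (46% higher, against 33.3%) genes, DESeq2 218 and the thinned libraries 58. The count was 65, 52 or 70 without Chrom3-5R replicate 1, 3 or 4 and 64, 54 or 67 without Chrom3-160R replicate 2, 3 or 4.

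**Figure D4:**
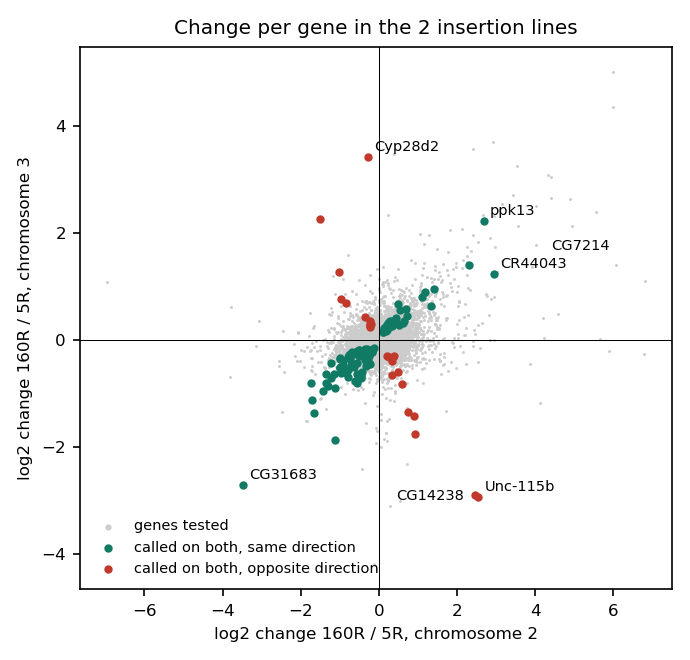
Log2 change 160R against 5R on chromosome 2 (horizontal axis) and on chromosome 3 (vertical axis) for the 13525 genes tested. Each point is a gene, and colours mark the 111 genes called on both in the same direction and the 24 called in opposite directions. Cyp28d2 lies at 3.42 on chromosome 3 and -0.28 on chromosome 2.

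The change itself differed between chromosomes for 983 genes, 528 with a more positive change on chromosome 3 and 455 with a more negative one. Cyp28d2 had the smallest p among these, with a difference of 3.7 ± 0.11 (edgeR adjusted p = 1.2e-12). Unc-115b and p24-2 rose on chromosome 2 (2.54 and 2.46) and fell on chromosome 3, with differences of -5.48 ± 0.3 and -5.36 ± 0.3. Both were also called higher in Chrom3-5R than in Chrom2-5R. Chrom2-160R and Chrom3-5R thus stood high and Chrom2-5R and Chrom3-160R low, a pattern that does not follow repeat length. Cyp9c1 and CR43787 differed by -1.92 ± 0.13 and -1.91 ± 0.13. The change of cytosolic ribosomal proteins was less negative on chromosome 3, with a median difference of 0.31 and 23 of 84 members called, none the other way (62 adjusted over the list alone; camera adjusted p = 6.07e-19, and adjusted p = 0.873 with an estimated correlation). Synaptic markers had a median difference of -0.22, with 10 of 24 members lower and 1, Rbp9, higher (13 and 1 adjusted over the list alone; camera adjusted p = 7.15e-05, and adjusted p = 0.873 with an estimated correlation). Fat body markers had a median difference of 0.38 with 4 of 18 called, Rfabg, Mtp, bmm and Obp99a (6 adjusted over the list alone; camera adjusted p = 0.0225, and adjusted p = 0.873 with an estimated correlation). Obp99a was lost there without Chrom2-5R replicate 2 (edgeR adjusted p = 0.0694) or 3 (0.0546) or Chrom2-160R replicate 3 (0.0535), in a range from 0.000235 to 0.0694. Upper-quartile scaling split the count 369 and 755 (32.8% more positive, against 53.7%). The count was 584 to 1695 over libraries left out, beyond 1.5-fold without Chrom2-5R replicate 1 (632), 3 (584) or 4 (1695), Chrom2-160R replicate 2 (600), Chrom3-5R replicate 1 (597) or Chrom3-160R replicate 1 (636) or 2 (625).

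The control lines also differed from each other, which gives the size of line differences with the short repeat alone. Cytosolic ribosomal protein, phototransduction, heat shock and activity-regulated genes were called lower as lists in Chrom3-5R than in Chrom2-5R heads, and small nucleolar RNAs, of which 203 of 213 overlap another gene, higher. These calls were lost with an estimated correlation (camera adjusted p = 0.459, 0.26, 0.545, 0.614 and 0.213, in the same order). CG11313 stood at 23.2 ± 5.09 CPM in Chrom3-5R and 0.253 ± 0.219 in Chrom2-5R, a log2 difference of 6.37 ± 0.31 (edgeR adjusted p = 1.3e-08). In all 4103 genes were called (30.3%), 2086 higher and 2017 lower, and 874 at 1.5-fold or more, of which 597 were higher (68.3%) and 277 lower. After thinning 3109 genes were called, so depth is not the whole cause. Line and any batch go together in these groups and cannot be separated here.

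Further genes higher in Chrom3-5R were CG14238 (3.27 ± 0.21), Cyp316a1 (2.62 ± 0.22), CG11052 (2.41 ± 0.13), CG42876 (2.36 ± 0.15), Ugt37b1 (2.26 ± 0.25), and Unc-115b and p24-2 (2.6 ± 0.22 and 2.52 ± 0.22), which overlap. Lower were kl-5 and Ory, male fertility genes of the Y chromosome, by -1.94 ± 0.46 and -2.58 ± 0.69 (edgeR adjusted p = 0.0069 and 0.014), the DNA photolyase phr (-1.92 ± 0.12), CR45232 (-1.84 ± 0.34), CG14190 (-1.68 ± 0.21) and CG9150 (-1.66 ± 0.22), and Cyp4p2 (-2.23 ± 0.1) and CG34215 (-1.62 ± 0.13), both with abundant overlapping partners. Ory was lost without Chrom2-5R replicate 2 (edgeR adjusted p = 0.0505, in a range from 0.0011 to 0.0505).

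Cytosolic ribosomal proteins were lower in 80 of 84 (81 adjusted over the list alone; median -0.53; camera adjusted p = 5.19e-37, and adjusted p = 0.459 with an estimated correlation), with RpS24 at -0.67 ± 0.06 and RpL13 at -0.68 ± 0.07. Small nucleolar RNAs were higher in 104 of 213 and lower in 1, snoRNA:Psi28S-291 (116 and 1 adjusted over the list alone; median 0.67; camera adjusted p = 9.42e-16, and adjusted p = 0.213 with an estimated correlation), but 203 of the 213 overlap another gene. For example, snoRNA:lola-c (1.52 ± 0.1) lies within lola, which has 178 times its counts. Photoreceptor genes were lower in 19 of 29 and higher in 2, rdgA and ninaD (21 and 2 adjusted over the list alone; median -0.35; camera adjusted p = 2.51e-07, and adjusted p = 0.26 with an estimated correlation). The light-gated channel trp changed by -0.54 ± 0.06 and the rhodopsins Rh4 and Rh6 by -0.59 ± 0.07 and -0.53 ± 0.07. Heat shock genes were lower in 6 of 21 (6 adjusted over the list alone; median -0.2; camera adjusted p = 0.0134, and adjusted p = 0.545 with an estimated correlation), with Hsc70-4 at -0.53 ± 0.08 and stv at -0.41 ± 0.06. Activity-regulated genes were lower in 6 of 10 (6 adjusted over the list alone; median -0.26; camera adjusted p = 0.0118, and adjusted p = 0.614 with an estimated correlation), among them Arc1 (-0.48 ± 0.09) and Jra, the fly Jun (-0.34 ± 0.05). Unfolded protein response genes were lower in 8 of 19 and higher in 2, Atf6 and Der-1 (9 and 2 adjusted over the list alone; median -0.08; camera adjusted p = 0.0301, and adjusted p = 0.614 with an estimated correlation), with Xbp1 at -0.31 ± 0.05 and crc at -0.29 ± 0.05. Der-1 was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.0784), 2 (0.0634) or 4 (0.0526) or Chrom3-5R replicate 2 (0.121) or 3 (0.0555), in a range from 0.00761 to 0.139. The snoRNA:Psi28S-291 call was lost without Chrom2-5R replicate 1 (edgeR adjusted p = 0.0873) or 3 (0.058) or Chrom3-5R replicate 1 (0.0659) or 4 (0.0626), in a range from 0.0056 to 0.0873. Upper-quartile scaling split the calls 2408 and 1490 (61.8% higher, against 50.8%). A fit of the genes that overlap no other gene called 1724.

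Genes that mark transgenes, sex and neurons were read in every comparison. The eye colour gene v changed by -0.61 ± 0.06 on chromosome 2 (edgeR adjusted p = 3.3e-06), and its log2 value on chromosome 3 was -0.17 (0.18). The white gene w, a common transgene marker, changed by 0.49 ± 0.08 on chromosome 2 (edgeR adjusted p = 0.00048), with a value of 0.08 on chromosome 3 (0.73), but kirre overlaps it with 6.62 times its counts. The body colour gene y changed by 0.42 ± 0.12 on chromosome 2 (edgeR adjusted p = 0.019), with a partner, CG32816, at 9.16 times its counts, and the call ended without Chrom2-5R replicate 3 (0.0718) or Chrom2-160R replicate 2 (0.0645), in a range from 0.0112 to 0.0959. On chromosome 3 its log2 value was -0.02 (edgeR adjusted p = 0.96). Of the dosage compensation RNAs, roX1 changed by -0.19 ± 0.06 on chromosome 2 (edgeR adjusted p = 0.03), with a value of -0.12 on chromosome 3 (0.41). Its call ended without Chrom2-5R replicate 1 (0.114 by edgeR) or 3 (0.0709) or Chrom2-160R replicate 1 (0.0797) or 4 (0.0634), in a range from 0.0127 to 0.132. roX2 (0.06 and -0.01) and the neuronal gene elav (0.09 and -0.08) were not called on either chromosome. The yolk protein gene Yp1, a female marker, changed by -1.7 ± 0.51 on chromosome 2 (edgeR adjusted p = 0.027), with a value of -0.49 on chromosome 3 (0.67). Its call ended without Chrom2-5R replicate 3 (0.091 by edgeR) or any 1 of the Chrom2-160R libraries (0.0546 to 0.0679), in a range from 0.00479 to 0.0914.

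Between the 5R lines, elav was higher in Chrom3-5R by 0.21 ± 0.06 (edgeR adjusted p = 0.0078) and roX1 lower by -0.28 ± 0.06 (0.0026). The y gene was higher by 0.39 ± 0.12 (edgeR adjusted p = 0.022), a call that ended without Chrom2-5R replicate 3 (0.0815), Chrom3-5R replicate 1 (0.075) or Chrom3-5R replicate 4 (0.0631), in a range from 0.0126 to 0.0882. The log2 differences of w (0.16), v (0.05), roX2 (0.01) and Yp1 (-0.78) were not called (edgeR adjusted p = 0.17, 0.54, 0.92 and 0.22).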

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

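The tests of muscle and cuticle genes below, and the intervals given with them, were chosen after the results were seen, and the bounds for thorax tissue, for the 2 libraries and for a maturation or age axis were changed after their values were seen.

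Counts from other splits of the libraries were set beside the real ones. With 35 splits the share can be no lower than 1 of 35. In a mixed split the real group difference adds to the spread within groups and so lowers the count. The splits do not bear on differences of line or batch. For chromosome 2, 1 of 35 splits of the 8 libraries, the real one, gave as many genes as the 3535 called, and the highest other gave 504. For chromosome 3 it was 1 of 35 (285, highest other 7), between the 5R lines 1 of 35 (4103, highest other 9), for the mean of both chromosomes 1 of 100 (3140, highest other 1182) and for genes shared by both 1 of 100 (111, highest other 0). For the difference between chromosomes 3 of 100 splits gave as many genes as the real 983, and the highest other, with 2312, kept all 8 labels of the chromosome 2 libraries and 2 of the 8 labels of the chromosome 3 libraries. Chance cannot be excluded for the number of lists called, since 20 of 35 splits gave as many as the 7 on chromosome 2 (highest other 11), 7 of 35 as many as the 12 on chromosome 3 (highest other 14), and 17 of 100 as many as the 10 of the mean (highest other 12).

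In 33 of 406 groups of 4 libraries checked (8.1%, with 5% by chance), 1 library stood apart from the others, its gap to the nearest being beyond Dixon's 95% critical value as a share of the group's range. In Chrom2-160R replicate 1 this held for CG8736 (gap 0.993 of the range), CG34327 (0.878), CG13056 (0.838), CG16884 (0.962), CG13183 (0.9), up (0.853), TpnC25D (0.835), Tm1 (0.936), to (0.85), bw (0.834), Cpr76Bd (0.958), CG10936 (0.904) and the medians of the muscle list (0.922) and the male germline list (0.87). In Chrom2-160R replicate 4 it held for CG12256 (0.907) and Nup44A (0.851). In Chrom2-5R it held for Acp1 (0.846), CG7203 (0.862), Mtp (0.897), cry (0.886) and bw (0.965) in replicate 4, ACC (0.984) and stv (0.992) in replicate 1, snoRNA:lola-c (0.904) in replicate 2, and CG1092 (0.856) and the median of the nucleocytoplasmic transport list (0.952) in replicate 3. On chromosome 3 it held for Obp99a (0.907) and elav (0.898) in Chrom3-5R replicate 1, stv (0.913) in Chrom3-5R replicate 2, Cyp28d2 (0.848) in Chrom3-5R replicate 3, rdgC (0.856) in Chrom3-160R replicate 2 and Cpr76Bd (0.846) and CG13056 (0.875) in Chrom3-160R replicate 4.

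For further named genes the 160R change differed between the chromosomes by edgeR. Values are the chromosome 3 minus the chromosome 2 log2 change. Differences above 0 were found for Cyp28d2 (3.7), CG18673 (3.12), Obp99a (2.37), CG34215 (2.28), CG12256 (2.22), CR43477 (2.2), CG33926 (2.14), CG15120 (1.8), CG8665 (1.69), CG6280 (1.39), Cyp4p2 (0.92), mRpS28 (0.83), LM408 (0.71), mRpL37 (0.59), cry (0.57), Rbp9 (0.52), Mtp (0.5), GstE9 (0.47), DnaJ-1 (0.44), v (0.44), Cyp9b2 (0.43), RpL37a (0.41), Rfabg (0.4), RpS24 (0.4), ref(2)P (0.37), RpLP0 (0.36), Mip (0.36), Stat92E (0.27) and PEK (0.21). Differences below 0 were found for Unc-115b (-5.48), p24-2 (-5.36), CG14238 (-3.39), CG8757 (-2.68), Cyp9c1 (-1.92), CR43787 (-1.91), Hsp23 (-1.73), CR44043 (-1.71), upd3 (-1.37), Ilp3 (-0.77), CG42876 (-0.75), IM2 (-0.7), w (-0.42), Hsp67Bc (-0.41), bru-3 (-0.34), ITP (-0.33) and DAT (-0.32). Among the lists the median difference was 0.38 for fat body markers, 0.31 for cytosolic ribosomal proteins and -0.22 for synaptic markers, each called by camera. These calls were lost with an estimated correlation (camera adjusted p = 0.873 for each), and fry called 1 list. The Obp99a difference was lost without any 1 of 3 libraries named above (edgeR adjusted p 0.0535 to 0.0694, in a range from 0.000235 to 0.0694).

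More genes were called on chromosome 2 (3535) than on chromosome 3 (285). Depth argues the other way, and after thinning the chromosome 2 count was 20.2 times that on chromosome 3. No single library is the whole cause, since the ratio was at least 9.3 without any 1. Whether Chrom2-5R itself stands apart cannot be told. It lay farther than Chrom2-160R from the mean of the chromosome 3 groups for 53.9% of the chromosome 2 calls (95% interval over genes 52.2 to 55.5). Of these calls, 636 higher and 799 lower were also called with that sign between the 5R lines (267.6 and 268.4 if independent). Both comparisons use Chrom2-5R, which raises these counts. Insertion site and genetic background stay open and were not tested.

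The muscle and cuticle lists were called higher in the 160R libraries by camera in the mean of both chromosomes, with medians of 0.33 and 0.27 and 13 of 21 and 28 of 88 members called higher (adjusted p = 0.609 and 0.444 with an estimated correlation). Whether thorax tissue was left on some heads cannot be told, since the flight muscle genes Act88F, fln and TpnC4 (0 of 3 called) had a median log2 change of 0.06 that covers -0.26 on chromosome 2 and 0.25 on chromosome 3, and their centred median was highest of each 160R group in Chrom2-160R replicate 1 (0.65) and Chrom3-160R replicate 4 (0.38). Without these 2 libraries the muscle and cuticle medians were 0.16 (95% interval over genes 0 to 0.26) and 0.13 (0.07 to 0.27). Whether the 2 carry more than 0.5 of the change cannot be told. They were chosen as highest in cuticle genes, with no like removal from 5R, and the intervals are over genes. A maturation or age axis that also varies within groups cannot be told apart from thorax tissue, since either would tie the 2 lists together (r = 0.64 for deviations of their medians from group means, without the 2 libraries farthest from the rest). The exact age of each library within 5 to 8 days is not given, and an effect of the repeat stays open.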

How the results depend on the processing

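The tests of genes that overlap no other gene, of thinned libraries and without the 2 libraries highest in cuticle genes were chosen after the data were seen. Where only a count is given, the cause of its move was not tested, apart from fewer genes tested or fewer libraries. The chromosome 2 count (3535) was 2293 with only the groups compared, 1720 for genes that overlap no other gene and 738 at 1.5-fold or more. The chromosome 3 count (285) was 523 with DESeq2, 144 for genes that overlap no other, 140 after thinning and 96 at 1.5-fold, and ranged from 167 to 337 over libraries left out. It was 176 and 167 without Chrom3-5R replicates 1 and 3, and 181 and 170 without Chrom3-160R replicates 2 and 3. The mean of both (3140) was 1585 for genes that overlap no other and 390 at 1.5-fold. The difference between chromosomes (983) was 479 and 314 by the same choices, and 584 to 1695 over libraries left out (632, 584 and 1695 without Chrom2-5R replicates 1, 3 and 4, 600 without Chrom2-160R replicate 2, 597 without Chrom3-5R replicate 1, 636 and 625 without Chrom3-160R replicates 1 and 2). The 5R lines (4103) gave 1724 and 874. The shared count (111) was 218 with DESeq2, 60 for genes that overlap no other, 58 after thinning, 23 at 1.5-fold and 52 to 166 over libraries left out (65, 52 and 70 without Chrom3-5R replicates 1, 3 and 4, 64, 54 and 67 without Chrom3-160R replicates 2, 3 and 4).

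With an estimated correlation, camera called 0 lists on chromosome 2, 0 on chromosome 3 and 0 in the mean (2, 4 and 3 at an unadjusted p below 0.05). By fry it was 12, 0 and 12 lists (16, 9 and 15 unadjusted). The chromosome 2 list count (7) ranged from 6 to 12 over libraries left out, with 12 without Chrom2-5R replicate 2. Over the list alternatives 454 calls were kept and 61 lost.

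With the replicate number as a block the counts were 3052 on chromosome 2, 197 on chromosome 3, 2711 in the mean, 647 for the difference, 3717 between the 5R lines and 72 shared. Libraries with the same number deviated together with correlations of only -0.15 to 0.14, so the numbers do not pair the libraries. Without the 2 libraries highest in cuticle genes the counts were 3281, 313, 2761, 1334, 4510 and 105, in the same order.

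For named genes 7855 alternatives kept the call or its absence, 529 ended a call, 1 made one and 0 turned a direction. Thinning ended 43 calls, and moved the chromosome 2 count from 3535 to 2826 and the chromosome 3 count from 285 to 140.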

Other observations

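The list of larval serum protein and larval fat body genes, the cuticle list and the comparison of muscle with cuticle genes were chosen after the data were seen.

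Genes of the larval fat body went both ways in 160R heads. Of 6 measured, 2 rose in the mean of both chromosomes and 2 fell (3 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.708). Its median in centred log2 CPM was 1.33 in Chrom2-160R replicate 1 and -0.63 to -0.52 in the other Chrom2-160R libraries, and 1.04 in Chrom3-160R replicate 4 and -0.83 to 0.5 in the other Chrom3-160R libraries. The storage proteins Lsp2 and Lsp1beta changed by -1.68 ± 0.45 and -1.33 ± 0.23 (edgeR adjusted p = 0.019 and 0.0015). Lsp1beta stood at 99.1 ± 30.6 CPM in Chrom2-5R and 38.5 ± 7.56 in Chrom2-160R, and at 189 ± 34.7 and 77.1 ± 35.4 on chromosome 3. The rises were in genes with few counts, Fbp1 (3.32 ± 1.11) and Fbp2 (2.5 ± 0.83; edgeR adjusted p = 0.048 and 0.045). Fbp1 was lost, as above, without any 1 of 11 libraries (edgeR adjusted p 0.0543 to 0.17, in a range from 0.0362 to 0.269). Fbp2 was lost without any 1 of the 16 except Chrom2-160R replicates 3 and 4 and the 4 Chrom3-160R libraries (edgeR adjusted p 0.0551 to 0.131, in a range from 0.000466 to 0.131).

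Genes of chromosome 4 and of the Y chromosome differed between the 5R lines. Of 105 chromosome 4 genes tested, 77 were higher in Chrom3-5R and 3 lower, with a median log2 difference of 0.3, and 0.14 between the 160R lines. On chromosome 2 the 160R change of these genes had a median of 0.16, with 44 higher and 5 lower (46.7% called, against 26.1% of all genes). On chromosome 3 the median was -0.01, with 1 higher and 1 lower. Of 10 genes on the Y chromosome, 5 were lower in Chrom3-5R and 0 higher.

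For the chromosome 4 genes, depth was not the whole cause. After thinning the median difference was still 0.28 (95% interval over genes 0.23 to 0.33). Reads from introns and repeats cannot be excluded. The 52 genes with an exonic share of their span above 53.7% also had a median of 0.28 (0.22 to 0.33). In the 52 with a lower share it was 0.33, so the difference was not confined to these. Spans in the upper set still hold introns, and repeat content was not measured. Genetic background of the lines stays open and was not tested.

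The chromosome 2 change and the difference between the 5R lines share the Chrom2-5R libraries. Their log2 values were correlated with r = 0.42 (0.6 in 20 simulations of unchanged groups, 0.22 with the controls split in 6 ways) and a covariance of 0.0653 (0.0271 simulated, 0.0402 split). The same sign was found for 66.4% of genes (69% simulated, 59.6% split). Split controls share no library, so shared noise was not the whole of the covariance.

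Over the 16 libraries, deviations of the muscle and cuticle list medians from their group means were correlated (Pearson r = 0.81, permutation p = 0.004; Spearman rho = 0.64, permutation p = 0.02; 1 relation computed). On chromosome 3 cuticle genes were higher in 3 of 88 (Cpr57A, Cpr72Ec and Cpr67B) and lower in 2 (TwdlV and TwdlG; 4 and 2 adjusted over the list alone; median 0.28; camera adjusted p = 2.59e-05, and adjusted p = 0.409 with an estimated correlation). Without the 2 libraries highest in cuticle genes the median was 0.15. Cpr72Ec was lost without Chrom3-5R replicate 2 (edgeR adjusted p = 0.0523) or 3 (0.0718) or Chrom3-160R replicate 2 (0.065) or 3 (0.0739), in a range from 4.4e-05 to 0.116. Cpr67B was lost without any 1 of the 8 chromosome 3 libraries except Chrom3-160R replicate 1 (edgeR adjusted p 0.0965 to 0.181, in a range from 0.0121 to 0.181), and TwdlG without any except Chrom3-5R replicate 2 and Chrom3-160R replicate 1 (0.0691 to 0.169, in a range from 0.00596 to 0.228).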
